A study of Mus musculus with 103 samples.

How the data were processed

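RNA sequencing measured transcript levels in muscle stem cells of C57BL/6 mice in 2 formats, bulk libraries and single-cell wells. Per the labels, bulk RNA was isolated with a Qiagen micro kit and amplified to cDNA with a NuGEN Ovation kit, and libraries were made with a TruSeq kit. The labels name STAR as the aligner and mm10 as the genome build. Its version, the annotation, the strandedness and the tool that turned alignments into expression values are not given in the sources used here. The labels describe culture of the isolated cells in a medium with fibroblast growth factor 2, without saying whether RNA was taken before or after culture, and the design text calls the cells myoblasts. They give neither a sort gate nor surface markers.

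The deposited values of both tables are TPM, per the labels: transcript abundances scaled to a common total in each library. Library totals lay between 999999.2 and 1000000.9 in the 8 bulk columns, as that unit requires. TPM are shares of a library, so a rise of some genes lowers others, and read counts or depth per library cannot be read from them. No depth, counting interval or detection limit was therefore computed for bulk values. The precision of a bulk group rests on the spread between its 2 or 3 libraries.

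The bulk table held 45798 entries. Of these, 43283 carried an Ensembl gene ID, 92 were spike-in RNAs and 2423 had neither and were left out, as their labels could not be tied to 1 gene each (564 labels occurred more than once). GENCODE vM21, an annotation of the mm10 assembly, held 42782 of the 43283 IDs and gave the gene positions. The table of wells held 43282 IDs in 45797 entries.

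Groups were taken from the labels. The 3 young, 2 middle-aged and 3 old bulk libraries came from separate mice according to the design text, and the wells from 1 mouse per age. Replicate numbers were not treated as pairs: after removal of the group means, libraries with the same number correlated at r = -0.012 to 0.005 across genes.

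Bulk comparisons used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), for the 22492 genes with a mean TPM of at least 1 over the 8 libraries. All 8 libraries were fitted together with a mean per age group, an intensity trend of the variance and two-sided moderated tests. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. No other tool was run for single genes. Cd47 was also tested with an exact two-sided permutation test in R 4.3.3. On simulated data with 200 changed genes per run, checked for the old against young comparison alone, the limma test called 0.22% of genes changed by 1 log2 unit, 3.64% at 2 units and 22.42% at 3 units. It made 16 false calls among 357 and 0 calls in runs with no changed gene. Changed genes were drawn only from those with a mean log2(TPM + 1) at or above that of 5 TPM. Noise was normal with a floor at 0, while 66.1% of the tested genes were listed at 0 in at least 1 library. These shares may therefore not hold for such genes. A list of 15 genes shifted by 1 unit was called in 75% of 20 runs. Noise was drawn independently for each gene, so that share does not carry over to lists whose members move together.

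Before the data were examined, 37 gene lists for processes and cell types were fixed, and 36 of them were tested. The list of sex-linked genes was only described. The camera test of limma compared the members of a list with all other genes at a preset correlation of 0.01, and its p values were adjusted over the 36 lists. It was repeated with a correlation estimated from the data. The fry test, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, was the other list test. Within each list, single genes were also adjusted over the list alone.

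Wells came from 1 mouse per age, so no test between ages was made for them. Shares of wells with a gene at 1 TPM or more are given with exact Clopper-Pearson 95% intervals. Where a gene was found in 0 wells, the upper limit is 3 wells of the total. Intervals and limits cover counting error between wells only. The median difference of mean log2(TPM + 1) of a list, old minus young, was placed among 10000 random lists matched on expression. A list was set apart where it lay below the 2.5 or above the 97.5 percentile. This covered 26 lists with enough members found in at least 10% of wells, among 3852 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

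Named genes followed a rule that was also set before the data were examined. It always took Cd47, Thbs1, Sirpa, Pax7, Myf5, Myod1, Myog, Calcr, Cd34, Mki67, Cdkn2a, Cdkn1a, Hpgd and Ptger4. Of genes past the threshold with a mean TPM of at least 5 and groups that do not overlap, it took the 10 with the largest change in each direction for old against young, and 5 for the other bulk comparisons. From each list past the threshold or described, it took up to 4 members with the smallest p. In wells it took, among genes at 1 TPM or more in at least 25% of the wells of a mouse, the 10 largest differences in each direction, leaving out ribosomal, mitochondrial and model genes. Genes named beyond it are marked as chosen after their values were seen.

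Alternatives changed the pseudocount, the expression filter, the scaling (quantile normalization, median-ratio scaling, and rescaling without mitochondrial and ribosomal protein genes), the libraries in the fit, a replicate block, the variance model and library weights. Each of the 8 bulk libraries was also left out in turn. For wells they changed the average, the pseudocount, the wells kept and the scaling. A filter at a mean of 20 TPM, a filter on values above 0 in all 8 libraries, rescaling of wells without spike-ins, and the test of old against the 5 other libraries were added after seeing the data.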

Results

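RNA was sequenced from muscle stem cells of mice at 3 ages, to ask how the cells' transcripts differ with age and what happens to Cd47. Cd47 encodes a membrane protein that tells phagocytes not to engulf a cell and that also binds thrombospondins. Muscle stem cells lie quiescent beneath the basement membrane of muscle fibres and divide after injury to repair them, a capacity that declines with age. The bulk libraries came from 3 young mice, 2 middle-aged mice (12 and 13 months) and 3 old mice (24 months). For the young bulk libraries the labels give 3 months in a field and 2 months in a description. The labels name the source as muscle stem cells, while the design text calls the cells myoblasts, the dividing progeny of stem cells. Single cells came from 64 wells of 1 young mouse and 31 wells of 1 old mouse.

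The bulk libraries were variable, even within an age. Across genes, pairs of libraries correlated at r = 0.546 to 0.749 (genes are not independent replicates). Pairs within the young group reached 0.616 to 0.652, the middle-aged pair 0.546 and pairs within the old group 0.724 to 0.749. Between 12849 and 17114 genes were found at 1 TPM or more per library. Mitochondrially encoded RNA made up 38.73 ± 1.09% of TPM in young (mean ± SD), 37.44 ± 6.75% in middle-aged and 39.62 ± 6.03% in old libraries. Of the genes with a mean of at least 5 TPM, 39.1% were listed at 0 in at least 1 library, and 11.6% of those with a mean of at least 20 TPM. Even among genes of the proteasome, which nearly every cell needs, 19 of 47 were listed at 0 somewhere. Values at 0 are therefore given library by library and not read as absence.

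Cd47 was the gene of first interest in old against young muscle stem cells. It lies on chromosome 16 (49800533 to 49915010, plus strand), with no other coding gene across it. Its level was 75.62, 65.19 and 86.02 TPM in the 3 young libraries and 106.53, 151.02 and 132.47 TPM in the 3 old libraries, so every old library lay above every young one. The difference was 0.77 log2 units (SE 0.31, 95% interval 0.07 to 1.46, 1.70-fold). An exact two-sided permutation test gave p = 0.1, the smallest that its 20 splits can give. Adjusted over all genes, p was 0.815, and 0.158 adjusted over the list alone for CD47 ligands and receptors. The 2 middle-aged libraries, at 74.52 and 67.14 TPM, lay within the young range.

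Other genes fixed in advance give the state of the cells. Thbs1, a secreted thrombospondin that binds CD47, averaged 12.71 ± 1.06 TPM in young and 28.12 ± 15.16 TPM in old libraries (log2 difference 0.96, and 0.57 without old library 2; adjusted p = 0.839), and 42.11 ± 13.19 TPM in middle-aged ones. The phagocyte receptor for CD47, Sirpa, had 20.98 ± 14.75 and 20.99 ± 13.58 TPM in young and old (log2 difference 0.08, and -0.47 without young library 3 or -0.39 without old library 1). Pax7, the transcription factor that marks muscle stem cells, stood at 290.83 ± 37.39 TPM in young and 217.04 ± 30.71 TPM in old libraries (log2 difference -0.42, adjusted p = 0.839). The myogenic factor Myf5 had 244.90 ± 86.16 and 195.45 ± 85.48 TPM, and Myod1, which is induced on activation, 19.02 ± 13.58 and 13.20 ± 6.08 TPM. Calcr, a calcitonin receptor that holds the cells quiescent, had 244.12 ± 89.00 and 165.63 ± 54.63 TPM, and the surface sialomucin Cd34 had 73.01 ± 16.31 and 63.63 ± 27.72 TPM. The log2 difference of Cd34 was -0.27 and 0.06 without old library 1, and that of Myod1 -0.31 and 0.21 without young library 1. The proliferation marker Mki67 had 5.62 ± 1.97 and 3.96 ± 1.60 TPM. Without 1 library the log2 difference lay between -0.67 and -0.02 for Myf5, -0.88 and -0.27 for Calcr, and -0.65 and -0.17 for Mki67. Myog, which drives differentiation, was listed at 0, 7.36 and 0 TPM in young, 0 and 0 in middle-aged, and 0, 0 and 21.56 TPM in old libraries.

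Cell cycle inhibitors and prostaglandin genes are followed in ageing muscle stem cells because senescence and loss of prostaglandin E2 signalling have been tied to their decline. Cdkn1a, a p53 target that arrests the cycle, had 35.38 ± 15.73 TPM in young and 125.94 ± 18.93 TPM in old libraries, with no overlap (log2 difference 1.90, adjusted p = 0.728). Its middle-aged libraries stood apart, at 41.22 and 268.84 TPM. Cdkn2a, the inhibitor linked with senescence in very old mice, was listed at 0 in all 8 libraries. Hpgd, the enzyme that degrades prostaglandin E2, was listed at 0 in all young and all old libraries and at 4.63 and 4.11 TPM in the middle-aged ones. Ptger4, a receptor for prostaglandin E2 whose locus overlaps Ttc33, had 5.25 ± 2.28 and 7.10 ± 1.67 TPM in young and old (log2 difference 0.42, and 0.16 to 0.69 without 1 library).

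**Figure D1:**
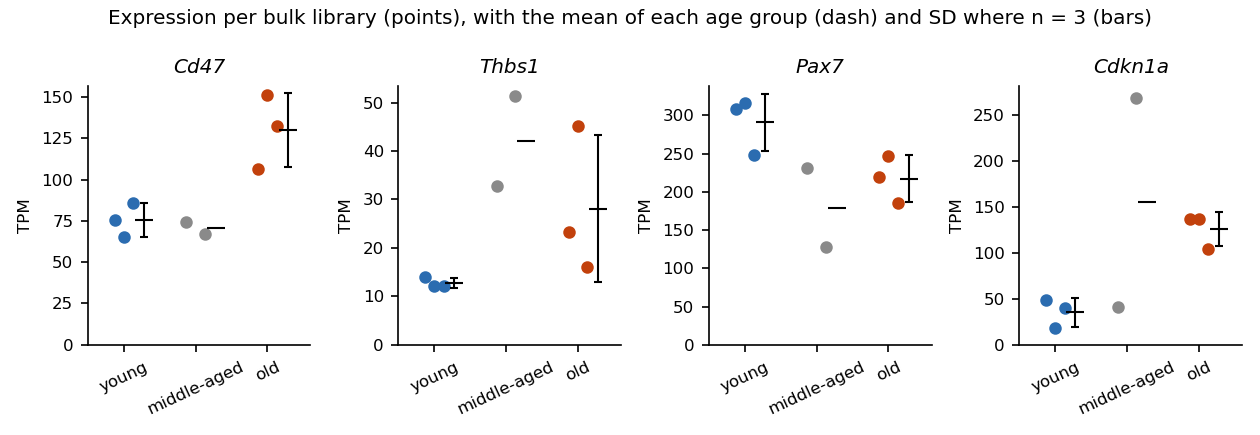
TPM of Cd47, Thbs1, Pax7 and Cdkn1a in each bulk library; the dash is the group mean and the bars the SD where n = 3. For each of these genes the limma adjusted p for old against young was above 0.05.

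Genes of Schwann cells, the glia that wrap motor axons in muscle, had the largest median difference between old and young libraries among the 36 lists. All 11 tested members were higher in old libraries, with a median difference of 2.55 log2 units (camera, adjusted p = 6.47e-13; adjusted p = 0.201 with an estimated correlation). The smaller p assumes a correlation of 0.01 between members. After removal of the group means they correlated at a median of 0.65, so that p overstates the evidence. By limma, 0 genes passed over all genes (9 at unadjusted p under 0.05), and 9 adjusted over the list alone. That number was 5 without young library 1 or young library 3, 4 without middle-aged library 1 or middle-aged library 2, and 2 without old library 2. Kcna1, a potassium channel of myelinated fibres (chromosome 6, 126640397 to 126646384, minus strand), had 7.65 ± 0.35 TPM in young and 82.49 ± 29.49 TPM in old libraries (log2 difference 3.22, adjusted p = 0.172, and 0.000364 adjusted over the list alone). The glial transcription factor Sox10 had 6.54 ± 4.85 TPM in young and 41.05 ± 12.16 TPM in old libraries (0.00848 adjusted over the list alone), and Mbp, a myelin membrane protein, 12.49 ± 11.92 and 133.09 ± 137.52 TPM (0.0156). In each of these genes, all 3 old libraries lay above all 3 young ones.

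Schwann cell genes were uneven among the old libraries, and most were highest in old library 2. For Mbp, old libraries 1, 2 and 3 had 26.12, 288.21 and 84.93 TPM. Prx had 12.24, 53.21 and 11.14 TPM there, and Mal 22.37, 92.26 and 22.89 TPM. For Mal, young library 3 at 26.54 TPM lay above old libraries 1 and 3. Sox10 and Cdh19 were highest in old library 1, at 51.99 and 33.22 TPM. Pmp22, a myelin protein that many other cells also make, reached 5013.11 TPM in old library 2 and 1424.72 and 1291.30 TPM in the other 2, against 1228.93 ± 496.95 TPM in young (0.126 adjusted over the list alone). Pmp22, Prx, Mal and Cdh19 were chosen after their values were seen. Of the 11 members, 0 belong to another of the lists. At the preset correlation the list stayed past the threshold without any 1 library.

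Markers of tendon cells and of connective tissue fibroblasts, which share muscle with its stem cells, were also higher in old libraries. All 8 tenocyte markers pointed up (median 1.47, adjusted p = 0.0012; adjusted p = 0.201 with an estimated correlation). Over all genes limma called 0 (3 at unadjusted p under 0.05), and 2 adjusted over the list alone; these were 0 without young library 2 or old library 3 and 1 without old library 2. Thbs4, a tendon thrombospondin, had 8.16 ± 1.5 TPM in young and 37.93 ± 17.92 TPM in old libraries (log2 difference 1.99, 0.0138 adjusted over the list alone). Fmod, a collagen-binding proteoglycan, had 3.28 ± 1.47 and 27.96 ± 13.93 TPM (2.71 log2 units, 0.0138). Among 15 fibroblast markers, 12 were higher and 3 lower (median 0.91, adjusted p = 0.0139; adjusted p = 0.269 with an estimated correlation). That list missed the threshold without young library 3 (0.11), old library 1 (0.103) or old library 3 (0.0928), by fry (0.161) and with a mean of at least 20 TPM (median 0.58, 0.0801), in a range of 0.000258 to 0.269 over its alternatives. Of these genes limma called 0 over all genes (6 higher and 2 lower at unadjusted p under 0.05), and 5 adjusted over the list alone, 4 up and 1 down. Without a library these were 1 (young library 1 or 3), 2 (old library 2) or 0 (young library 2, either middle-aged library, old library 1 or 3).

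Fibroblast genes past that narrower adjustment include secreted and matrix proteins. Dcn, a proteoglycan that binds collagen and growth factors, had 286.77 ± 47.24 TPM in young and 649.94 ± 254.31 TPM in old libraries (log2 difference 1.12, 0.0432 adjusted over the list alone). Mfap5, a microfibril protein, had 8.12 ± 6.96 and 34.65 ± 13.85 TPM (2.14 log2 units, 0.0432), and the complement inhibitor Serping1 had 344.30 ± 81.49 and 654.91 ± 130.01 TPM (0.93 log2 units, 0.0489). Ly6a, a stem cell antigen whose family members share sequence, was listed at 151.69, 72.34 and 0 TPM in young and at 0 in all 3 old libraries (0.0489), so its level is uncertain. Endothelial markers had a median of 0.60 (adjusted p = 0.104), smooth muscle 0.48 (0.251), lymphocyte 0.12 (0.475), macrophage -0.07 (0.285) and red blood cell genes -1.23 (0.285).

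Genes for signalling by interleukin 6 family cytokines through JAK and STAT proteins, which can drive muscle stem cells out of self-renewal, formed a further group. Of 20 genes, 18 were higher in old libraries (median 0.70, adjusted p = 0.000122; adjusted p = 0.201 with an estimated correlation). Single genes past the threshold in limma numbered 0 over all genes (7 at unadjusted p under 0.05), and 3 adjusted over the list alone, a count that held without any 1 library. Osmr, the oncostatin M receptor (chromosome 15, 6813577 to 6874969, minus strand), had 16.29 ± 4.02 TPM in young and 53.53 ± 9.42 TPM in old libraries (log2 difference 1.67, 0.0162 adjusted over the list alone). Socs3, the feedback inhibitor that STAT3 induces, had 94.99 ± 28.97 and 235.92 ± 37.31 TPM (1.33 log2 units, 0.0162). The shared receptor chain Il6st had 67.92 ± 11.99 and 143.24 ± 14.57 TPM (1.07 log2 units, 0.0348). For all 3, no old library overlapped a young one. The cytokine Il6 itself was listed at 6.45, 0 and 5.51 TPM in young and 32.98, 22.98 and 6.55 TPM in old libraries (0.107 adjusted over the list alone). In the same libraries the median differences of Schwann cell, tenocyte and fibroblast markers were 2.55, 1.47 and 0.91, which applies beside the inflammatory, matrix and metabolic groups as well. In the list, 3 of 20 members belong to another list as well, Il6 and Junb among them.

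Inflammatory and immediate early genes went the same way. NF-kappaB targets and cytokines had 19 of 23 members higher (median 0.57, adjusted p = 0.00169; adjusted p = 0.201 with an estimated correlation), and missed the threshold without old library 1 (0.0559). It also did with a mean of at least 20 TPM (median 0.45, 0.0801) and with values above 0 in all 8 libraries (0.41, 0.17), in a range of 0.000216 to 0.201 over its alternatives. By limma, 0 genes passed over all genes (4 at unadjusted p under 0.05) and 1 adjusted over the list alone, with 0 without young library 1 or 3 or old library 1 or 3. That gene was Cxcl10, a chemokine that interferon induces and whose locus overlaps Art3, with 3.20 ± 1.34 TPM in young and 29.56 ± 13.39 TPM in old libraries (log2 difference 2.80, 0.0163). Immediate early genes, which also respond to tissue dissociation, had 20 of 28 members higher (median 0.32, adjusted p = 0.00131; adjusted p = 0.21 with an estimated correlation). Their median was 0.56 without young library 1 and 0.21 without young library 3. By limma 0 passed over all genes and 0 adjusted over the list alone, with 7 at unadjusted p under 0.05. Without young library 1 the narrower adjustment gave 3, without either middle-aged library 2 and without old library 3 it gave 1. The growth arrest gene Gadd45b had 9.07 ± 0.61 and 37.98 ± 12.79 TPM (1.89 log2 units), its relative Gadd45g 7.33 ± 3.04 and 29.86 ± 13.19 TPM, and the nuclear receptor Nr4a2 38.76 ± 19.37 and 161.43 ± 103.58 TPM, each at 0.0543 adjusted over the list alone.

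Interferon response and antigen presentation bear on how immune cells see a cell. The interferon list had 20 of 25 members higher (median 0.59, adjusted p = 0.0361; adjusted p = 0.306 with an estimated correlation). It missed the threshold without young library 2 (0.0512), young library 3 (0.0931), old library 2 (0.1) or old library 3 (0.155), and by fry (0.164). The same held with a mean of at least 5 TPM (0.0981) or 20 TPM (0.329) and with values above 0 in all 8 libraries (0.152), in a range of 0.0186 to 0.329 over its alternatives. By limma 0 of its genes passed over all genes and 0 adjusted over the list alone, with 1 at unadjusted p under 0.05, and 1 passed the narrower adjustment without young library 1. Irf1, a transcription factor of that response whose locus overlaps a gene model, had 27.49 ± 10.37 TPM in young and 60.95 ± 13.27 TPM in old libraries (log2 difference 1.16). Of 16 genes for MHC class I presentation, 13 were higher (median 0.57, adjusted p = 0.0213; adjusted p = 0.201 with an estimated correlation), with fry at 0.146. The call was lost without young library 1 (0.165), old library 1 (0.0627) or old library 3 (0.0829), and with values above 0 in all 8 libraries (median 0.34, 0.108), in a range of 0.00278 to 0.201 over its alternatives. Without young library 2 the median was 1.00. Over all genes limma called 0 (1 at unadjusted p under 0.05), and 1 adjusted over the list alone, B2m. This light chain of MHC class I, overlapped by Patl2, had 230.99 ± 41.82 TPM in young and 563.71 ± 47.29 TPM in old libraries (log2 difference 1.30, 0.00812). The heavy chain gene H2-K1 had 163.44 ± 37.68 and 236.56 ± 20.56 TPM (0.55 log2 units, and 0.36 without young library 2).

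The list of CD47 ligands, receptors and other signals against phagocytosis had 14 of 19 members higher in old libraries (median 0.68, adjusted p = 0.0187; adjusted p = 0.201 with an estimated correlation). As fixed, the list mixes such signals with other genes, Calr, Lrp1, Elavl1, Set and Rac1 among them. The list as a whole therefore gives no direction for phagocytosis. It missed the threshold without young library 3 (0.0902), middle-aged library 1 (0.062), middle-aged library 2 (0.064), old library 1 (0.0583) or old library 3 (0.0829), where the median was 0.29. It also missed it with values above 0 in all 8 libraries (median 0.39, 0.1), in a range of 0.00951 to 0.201 over its alternatives. Of these genes limma called 0 over all genes (3 higher and 1 lower at unadjusted p under 0.05), and 2 adjusted over the list alone, B2m (0.00965) and Thbs4 (0.0239). That count was 1 without any 1 young library, old library 1 or old library 3, and 4 without either middle-aged library. Both belong to other lists too, as do Calr and Itgb1. Set, a phosphatase inhibitor, had 59.89 ± 9.24 TPM in young and 30.16 ± 1.30 TPM in old libraries, without overlap (log2 difference -0.96, 0.158 adjusted over the list alone).

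Extracellular matrix and basement membrane genes build the niche in which the stem cells rest. In old libraries 26 of 30 were higher (median 0.46, adjusted p = 3.23e-06; adjusted p = 0.201 with an estimated correlation), a list that fibroblasts and Schwann cells express too, though it shares 0 members with theirs. Single genes past the threshold in limma numbered 0 over all genes (8 at unadjusted p under 0.05), and 6 adjusted over the list alone. Without young library 2 or old library 3 these were 3, and without old library 1 they were 2. Lamb2, a laminin chain of the basement membrane (chromosome 9, 108479736 to 108490530, plus strand), had 22.34 ± 4.70 TPM in young and 92.54 ± 37.85 TPM in old libraries (log2 difference 1.95, 0.015 adjusted over the list alone). Another chain, Lamb1, had 8.22 ± 2.19 and 35.18 ± 8.75 TPM (1.97 log2 units, 0.015). Timp3, an inhibitor of matrix proteases that lies inside Syn3, had 91.89 ± 21.80 and 234.61 ± 30.67 TPM (1.36 log2 units, 0.015). The collagen cross-linking enzyme Lox was listed at 0, 0 and 3.71 TPM in young and 21.70, 12.17 and 11.56 TPM in old libraries (0.015).

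Glucose metabolism shifts when muscle stem cells activate. Of 19 glycolysis genes, 14 were higher in old libraries (median 0.36, adjusted p = 0.0227; adjusted p = 0.244 with an estimated correlation), with fry at 0.0558. The call was lost without young library 1 (0.0771), young library 3 (0.11), middle-aged library 1 (0.0895), middle-aged library 2 (0.0924), old library 1 (0.0559) or old library 3 (0.155). The median was 0.08 without old library 3, 0.23 without young library 3, 0.60 without young library 2 and 0.61 without old library 1. By limma, 0 genes passed over all genes (3 at unadjusted p under 0.05) and 1 adjusted over the list alone (2 without young library 3): Slc2a1, the glucose transporter of many proliferating and barrier cells, chromosome 4, 119108711 to 119137983. It had 24.34 ± 7.72 TPM in young, 74.97 ± 1.67 TPM in middle-aged and 146.65 ± 39.78 TPM in old libraries (log2 difference of old to young 2.56, adjusted p = 0.172, and 0.00102 adjusted over the list alone). The glycolytic enzyme Gpi1 had 10.87 ± 6.57 and 31.69 ± 7.96 TPM in young and old, and Aldoa, overlapped by Fam57b, 58.70 ± 4.29 and 91.33 ± 14.34 TPM. Wnt signalling, which can steer old satellite cells toward a fibrogenic fate, had 17 of 21 genes higher (median 0.43, adjusted p = 0.00888; adjusted p = 0.244 with an estimated correlation). It missed the threshold without young library 3 (0.0629), with a mean of at least 20 TPM (median 0.17, 0.328) and with values above 0 in all 8 libraries (0.36, 0.126), in a range of 0.00618 to 0.328 over its alternatives. Without young library 1 the median was 0.71. By limma 0 passed over all genes and 0 adjusted over the list alone, with 3 at unadjusted p under 0.05, and 1 passed the narrower adjustment without either middle-aged library. Tcf7l1, a repressor of Wnt targets, had 7.65 ± 5.09 and 23.08 ± 13.66 TPM.

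Cytosolic ribosomal protein genes, which set the capacity for protein synthesis, were the list that was lower in old libraries. Of 85 genes 59 were lower and 25 higher (median -0.32, adjusted p = 0.000419; adjusted p = 0.269 with an estimated correlation), with fry at 0.315. By limma 0 passed over all genes and 0 adjusted over the list alone, with 6 lower and 3 higher at unadjusted p under 0.05. Among the members with the smallest p, Rpl36a, a protein of the large subunit, had 226.58 ± 91.76 TPM in young and 89.41 ± 39.76 TPM in old libraries, and Rps18, of the small subunit and overlapped by Vps52, 459.95 ± 115.82 and 248.75 ± 61.47 TPM. Rpl13a, of the large subunit, differed by -0.71 log2 units. These genes have many processed pseudogenes, so their levels depend on how reads were assigned.

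Lists of stem cell state did not pass between old and young with all libraries in. The median was -0.15 for muscle stem cell identity (camera, adjusted p = 0.251; -0.34 and 0.022 without old library 3, in a range of 0.022 to 0.742 over its alternatives) and -0.04 for quiescence and Notch targets (0.285). Within the latter limma called 0 over all genes (1 higher and 1 lower at unadjusted p under 0.05) and 1 adjusted over the list alone, Gas1, a growth arrest protein that modulates hedgehog and GDNF signalling, with 195.22 ± 24.47 TPM in young and 74.12 ± 15.24 TPM in old libraries (log2 difference -1.40, 0.0253). Medians were 0.09 for myogenic differentiation (0.475), 0.55 for adult fibre genes (0.432), 0.29 for the cell cycle (0.43) and 0.30 for senescence (0.118). Among pathways studied in old satellite cells, p38 signalling had 0.54 (0.0665), TGF-beta 0.30 (0.0528), FGF signalling -0.01 (0.548) and prostaglandin E2 genes 0.17 (0.997). Senescence passed without young library 2 (0.0492) and TGF-beta without young library 2 (0.0249) or old library 2 (0.0265), in ranges of 0.0409 to 0.414 and 0.0249 to 0.214 over the alternatives. In the p38 list limma called 0 over all genes (2 at unadjusted p under 0.05) and 1 adjusted over the list alone. This was Mapkapk3, a kinase downstream of p38, at 0.000605, listed at 0 in all young and at 14.05, 13.10 and 20.35 TPM in old libraries.

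Lists for protein quality control, transcript processing and energy missed the threshold with all libraries in. Medians were -0.13 for heat shock genes (0.285), -0.09 for the unfolded protein response (0.526), 0.20 for autophagy (0.238), 0.18 for antioxidant genes (0.178) and 0.16 for nuclear oxidative phosphorylation genes (0.997). Proteasome genes had -0.03 (0.886), genes of the U1 snRNP and of 3-prime end processing 0.03 (0.93) and mitochondrially encoded genes -0.29 (0.0528). The last list passed as lower with a pseudocount of 0.1 (0.0259), without young library 1 (0.0232) and without old library 1 (0.0184), in a range of 0.0184 to 0.601 over its alternatives. For 4 lists the median, mean and test differed in sign: the U1 snRNP list was tested as down with a mean of 0.14, mitochondrially encoded genes down with 0.15, the proteasome down with 0.17 and FGF signalling down with 0.02.

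Over the whole transcriptome, limma called 0 of 22492 genes for old against young, with 1325 at unadjusted p under 0.05 (837 higher, 488 lower). Evenly spread p values would give 1124.6, and other splits of the young and old libraries gave 667 to 1015. The smallest adjusted p was 0.172. Of 11778 genes with a mean of at least 5 TPM, 1531 (13.0%) had groups that did not overlap, against a chance share of 10%. With camera, 13 of 36 lists passed, 12 higher and 1 lower, which was 8 without young library 3. With an estimated correlation camera called 0 lists, with 7 at unadjusted p under 0.05, and fry called 11, of which 8 were among the 13. The other 3 by fry were cell cycle inhibitors and senescence (0.0409), p38 signalling (0.0409) and TGF-beta signalling (0.049), and camera called the last 2 after quantile normalization (0.031 and 0.0403). The direction of 12 lists held under the 3 other scalings, and that of ribosomal protein genes under the 2 that keep them.

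**Figure D2:**
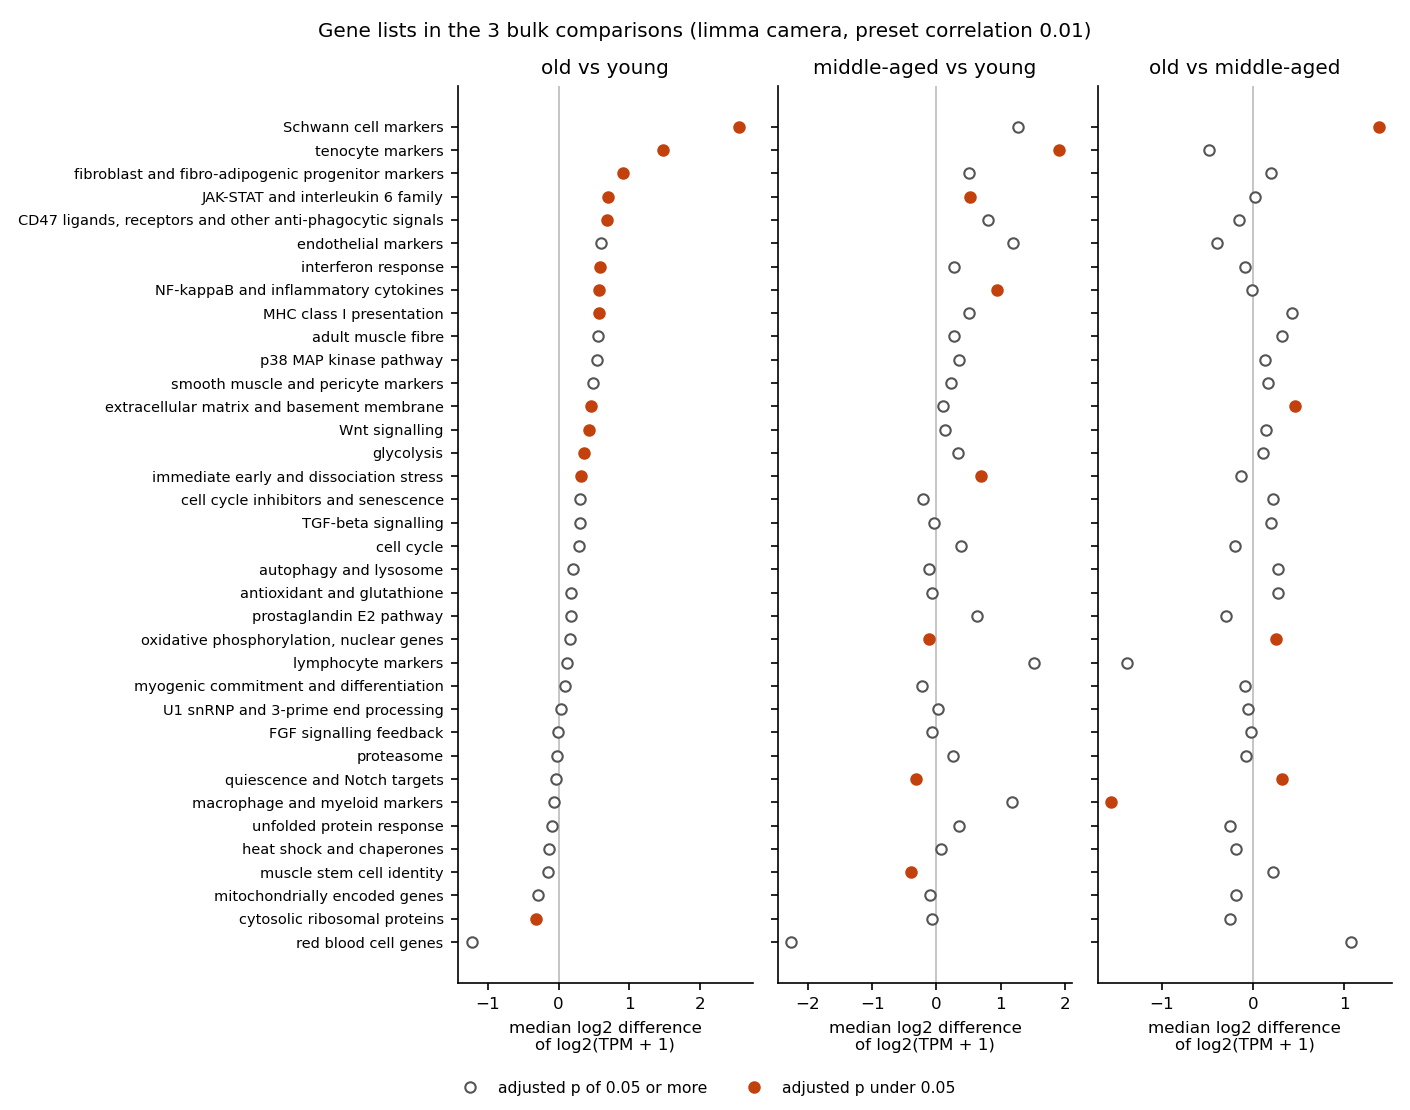
Median log2 differences of 36 gene lists in the 3 comparisons of ages; filled points have a camera adjusted p under 0.05 at the preset correlation.

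Middle-aged against young libraries ask which differences are present by about a year of age, when mice are not yet frail. The median of all genes differed by 0.18 log2 units, 0.13 after median-ratio scaling, 0.17 without mitochondrial and ribosomal protein genes and 0 after quantile normalization, and values are to be read against that shift. By limma 1 gene passed, Mapkapk3, which was listed at 0 in all 3 young libraries and at 55.56 and 92.16 TPM in the 2 middle-aged ones (adjusted p = 0.0498). The call was lost without young library 1 (0.099), 2 (0.134) or 3 (0.171) and without old library 1 (0.127), 2 (0.114) or 3 (0.177), and over all alternatives its adjusted p ranged from 0.00227 to 0.293. After quantile normalization 5 genes passed, 2 higher and 3 lower, against 1 higher and 0 lower. At unadjusted p under 0.05 there were 1750 genes, 1238 higher and 512 lower. Without overlap were 2623 of the 11778 genes (22.3%, chance 20.0%). In the p38 list it was the 1 gene past the threshold over all genes, and 1 passed adjusted over the list alone.

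Transcripts for interleukin 6 family cytokines, their receptors and STAT proteins were also compared at middle age. Of 20 JAK-STAT genes 17 were higher (median 0.52, adjusted p = 0.0153; adjusted p = 0.511 with an estimated correlation), a call lost without young library 3 (0.0878), middle-aged library 1 (0.0924) or middle-aged library 2 (0.74), by fry (0.0795) and with values above 0 in all 8 libraries (median 0.25, 0.0939). Over its alternatives the range was 4.98e-05 to 0.74, and the median was 0.29 without young library 3, 0.87 without young library 1 and 0.85 without middle-aged library 1. Over all genes limma called 0 (7 at unadjusted p under 0.05), and 4 adjusted over the list alone, which was 3 without young library 1 and 1 without any 1 of the other 7. Osmr stood at 111.38 ± 2.80 TPM against 16.29 ± 4.02 TPM in young (log2 difference 2.73, 0.00125 adjusted over the list alone), and Socs3 at 213.47 ± 30.02 TPM (1.19 log2 units, 0.0407). Stat3, the transcription factor of the pathway, whose locus overlaps Stat5a, had 50.49 ± 24.77 TPM in young and 196.40 ± 133.63 TPM in middle-aged libraries (0.0407). Il6 was listed at 37.01 and 51.64 TPM in the middle-aged libraries (0.0353). Beside these genes, markers of other cells had medians of 1.91 (tenocyte, adjusted p = 0.00717), 1.52 (lymphocyte, 7 higher and 0 lower, 0.0815), 1.27 (Schwann cell, 0.0802), 1.19 (endothelial, 0.308), 1.18 (macrophage, 10 of 14 higher, 0.308) and 0.51 (fibroblast, 0.386) in the same comparison.

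Inflammatory and immediate early genes followed. Of 23 NF-kappaB and cytokine genes 18 were higher (median 0.95, adjusted p = 0.00717; adjusted p = 0.476 with an estimated correlation), lost without young library 1 (0.0738) or middle-aged library 2 (median 0.48, 0.848), by fry (0.0551) and with values above 0 in all 8 libraries (0.49, 0.0813). Over its alternatives the range was 0.0065 to 0.848, and the median was 1.47 without middle-aged library 1. Of these genes limma called 0 over all genes (7 at unadjusted p under 0.05) and 3 adjusted over the list alone: Il6, Cxcl10 and Tnfaip2, each at 0.0347. The count was 0 without young library 1, young library 3, either middle-aged library or old library 3, 1 without old library 1 and 2 without old library 2. Cxcl10 had 21.21 ± 9.14 TPM, and Tnfaip2, a protein that TNF induces, was listed at 0 in all 3 young and at 15.86 and 14.11 TPM in the middle-aged libraries. The TNF receptor Tnfrsf1a had 14.91 ± 5.84 TPM in young and 43.88 ± 14.76 TPM in middle-aged libraries. Of 28 immediate early genes 21 were higher (median 0.70, adjusted p = 0.004; adjusted p = 0.476 with an estimated correlation), lost without middle-aged library 1 (0.126) or 2 (0.114). Single genes past the threshold in limma numbered 0 over all genes (9 at unadjusted p under 0.05) and 1 adjusted over the list alone, Fosl1, an AP-1 subunit overlapped by Ccdc85b, listed at 3.05, 0 and 0 TPM in young and 18.67 and 53.88 TPM in middle-aged libraries (0.0249). The count was 2 without young library 1 or middle-aged library 2, 3 without old library 3, and 0 without young library 2 or 3, middle-aged library 1 or old library 1 or 2. The zinc finger factor Egr2 had 99.02 ± 20.30 and 253.0 ± 65.50 TPM, and the stress factor Atf3 121.81 ± 5.26 and 236.76 ± 39.17 TPM. The medians of lymphocyte and macrophage markers, cells that express many of these genes, were 1.52 and 1.18 beside 0.95 and 0.70 for these lists.

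Genes of the stem cell state differed between middle-aged and young libraries in a way that rested on middle-aged library 2. Of 20 identity genes 17 were lower (median -0.39, adjusted p = 0.0153; adjusted p = 0.558 with an estimated correlation), and of 23 quiescence and Notch targets 16 were lower (median -0.31, adjusted p = 0.00717; adjusted p = 0.511 with an estimated correlation). Without middle-aged library 2 both were lost, with medians of -0.07 and -0.13 (0.643 each), and without middle-aged library 1 the medians were -0.76 and -0.68. By fry both were lost too (0.417 and 0.291), in ranges of 0.00866 to 0.643 and 0.00406 to 0.643 over the alternatives. In the identity list limma called 0 over all genes and 0 adjusted over the list alone, with 1 higher and 1 lower at unadjusted p under 0.05, and 4 without middle-aged library 1 and 1 without old library 3. Pax7 had 178.93 ± 72.95 TPM (log2 difference -0.75, and -0.33 without middle-aged library 2 or -1.18 without middle-aged library 1; adjusted p = 0.626), the chemokine receptor Cxcr4 58.62 ± 7.05 TPM in young and 29.80 ± 14.59 TPM in middle-aged libraries, and the proteoglycan Sdc4 271.49 ± 55.96 and 464.08 ± 137.92 TPM. In the quiescence list limma called 0 over all genes (2 at unadjusted p under 0.05) and 1 adjusted over the list alone, Gas1, at 56.57 ± 3.75 TPM (log2 difference -1.76, 0.0104). Spry1, an inhibitor of FGF signalling that keeps the cells quiescent, had 288.27 ± 82.58 and 161.75 ± 86.78 TPM, and the receptor Notch1 20.07 ± 6.00 and 6.59 ± 0.30 TPM. While these lists had negative medians, those of tenocyte, lymphocyte, Schwann cell, endothelial and macrophage markers were 1.91, 1.52, 1.27, 1.19 and 1.18.

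Tendon markers and respiratory chain genes were the other lists past the threshold at middle age. Of 8 tenocyte markers 7 were higher (median 1.91, adjusted p = 0.00717; adjusted p = 0.476 with an estimated correlation), lost without middle-aged library 1 (0.0835) or 2 (0.643). By limma, 0 genes passed over all genes (3 at unadjusted p under 0.05) and 2 adjusted over the list alone: Thbs4, at 31.91 ± 8.31 TPM (log2 difference 1.84, 0.0328), and Chad. Chad, a cartilage and tendon protein overlapped by Acsf2, was listed at 3.10, 0 and 0 TPM in young and 47.52 and 46.41 TPM in middle-aged libraries (0.00387). The count was 1 without young library 2, young library 3 or middle-aged library 2. Fmod had 24.11 ± 23.79 TPM. Of 79 nuclear oxidative phosphorylation genes 43 were lower and 35 higher (median -0.11, adjusted p = 0.0219; adjusted p = 0.476 with an estimated correlation), lost without young library 1 (0.157), middle-aged library 1 (median -0.32, 0.31) or 2 (-0.06, 0.0891). It was also lost after quantile normalization (-0.21, 0.0746), with a mean of at least 5 TPM (0.0542) or 20 TPM (0.186), with values above 0 in all 8 libraries (0.294) and by fry (0.341), in a range of 0.0148 to 0.476. Without young library 3 the median was -0.31. Over all genes limma called 0 (3 higher and 5 lower at unadjusted p under 0.05) and 2 adjusted over the list alone, a count of 0 without young library 1 or middle-aged library 1 and 1 without middle-aged library 2 or any 1 old library. Both were listed at 0 in the 2 middle-aged libraries: Ndufa7, a complex I subunit (46.38, 45.05 and 12.26 TPM in young, 0.00226), and Uqcrc1, a complex III subunit (45.82, 29.56 and 3.60 TPM, 0.0419). In that list 38 of 79 genes were listed at 0 in at least 1 library, and 9 in both middle-aged ones.

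With camera, 7 of 36 lists passed for middle age, 4 higher and 3 lower, which was 4 without middle-aged library 1 and 0 without middle-aged library 2. Camera with an estimated correlation called 0, with 3 at unadjusted p under 0.05, and fry called 3, of which 2 were among the 7 and the other was p38 signalling (0.0386). The other 29 lists had adjusted p from 0.0802, for Schwann cell markers (median 1.27, 8 of 11 higher), to 0.797. Schwann cell markers passed without young library 2 (median 1.26, 0.0399) or middle-aged library 1 (1.82, 0.0425), in a range of 0.0399 to 0.858. In 10 of those the median, mean and test differed in sign.

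Old against middle-aged libraries cover the later part of the ages sampled, in which muscle mass and repair decline in mice. By limma 0 genes passed, with 1392 at unadjusted p under 0.05 (526 higher, 866 lower) and a smallest adjusted p of 0.116. Without overlap were 2715 of 11778 genes (23.1%, chance 20.0%). Cd47 was higher in all 3 old libraries than in both middle-aged ones (log2 difference 0.85, adjusted p = 0.724). Camera called 5 lists, 4 higher and 1 lower, which was 2 without young library 1 or 2, 0 without middle-aged library 1 and 1 without old library 3. With an estimated correlation it called 0, with 1 at unadjusted p under 0.05, and fry called 0. Of the 31 lists not called, fibroblast markers passed without old library 2 (0.0326) and autophagy genes without young library 3 (0.0495), in ranges of 0.0326 to 0.726 and 0.045 to 0.821. With all libraries in, these 31 lists had adjusted p from 0.0752 to 0.986, and in 9 of them the median, mean and test differed in sign.

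Schwann cell markers were higher in old than in middle-aged libraries, 11 of 11 (median 1.38, adjusted p = 6.79e-06; adjusted p = 0.47 with an estimated correlation), lost without middle-aged library 1 (median 0.70, 0.263). The median was 0.72 without old library 2 and 2.11 without middle-aged library 2. By limma 0 passed over all genes and 0 adjusted over the list alone, with 3 at unadjusted p under 0.05, and 2 passed the narrower adjustment without middle-aged library 2. Kcna1 differed by 1.63 log2 units, and Cnp, a myelin phosphodiesterase overlapped by Dnajc7, had 18.82 ± 12.72 TPM in middle-aged and 61.29 ± 24.77 TPM in old libraries. Matrix genes were higher for 24 of 30 (median 0.46, adjusted p = 0.0013; adjusted p = 0.47 with an estimated correlation), lost without middle-aged library 1 (0.0758) or old library 3 (median 0.12, 0.0636). Of these genes limma called 0 over all genes (5 at unadjusted p under 0.05) and 1 adjusted over the list alone, Col15a1, a basement membrane collagen at chromosome 4, with 21.11 ± 4.24 and 92.30 ± 31.84 TPM (log2 difference 2.03, 0.0309). That count was 0 without any 1 young library, middle-aged library 2, old library 2 or old library 3, and 2 without middle-aged library 1. Sparc, a collagen chaperone, had 373.98 ± 24.82 and 727.33 ± 219.39 TPM.

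Respiratory chain genes make ATP, and Notch targets keep the cells quiescent. The middle-aged libraries are the ones compared with young, so low values in them enter both comparisons; between old and young the medians were 0.16 (adjusted p = 0.997) and -0.04 (0.285). Of 79 oxidative phosphorylation genes 48 were higher (median 0.25, adjusted p = 0.037; adjusted p = 0.47 with an estimated correlation). The call was lost without young library 1 (0.0934), young library 2 (0.0631), middle-aged library 1 (0.474), old library 1 (0.092), 2 (median 0.16, 0.0636) or 3 (0.06, 0.116). With values above 0 in all 8 libraries the median was 0.05 (0.915), and the call was also lost with a mean of at least 5 TPM (0.14) or 20 TPM (0.425) and after quantile normalization (0.0525), in a range of 0.0128 to 0.915. Without middle-aged library 2 the median was 0.11. Single genes past the threshold in limma numbered 0 over all genes (6 higher and 3 lower at unadjusted p under 0.05) and 2 adjusted over the list alone, Ndufa7 (38.02, 38.90 and 22.19 TPM in old, 0.00187) and Uqcrc1 (21.98, 44.25 and 22.53 TPM, 0.0148), a count of 1 without young library 1, middle-aged library 2, old library 1 or 3 and 0 without middle-aged library 1 or old library 2. Of 23 quiescence and Notch targets 17 were higher (median 0.32, adjusted p = 0.046; adjusted p = 0.559 with an estimated correlation), lost without young library 1 (0.0534), 2 (0.0631), middle-aged library 1 (median 0.57, 0.0537), 2 (-0.07, 0.57) or old library 3 (0.14, 0.259). It was also lost with a replicate block (0.21, 0.126), a pseudocount of 0.1 (0.0701), a mean of at least 5 TPM (0.129) or 20 TPM (0.404) and values above 0 in all 8 libraries (0.115), in a range of 0.0148 to 0.579. Its median was 0.49 without old library 1. By limma 0 passed over all genes and 0 adjusted over the list alone, with 1 at unadjusted p under 0.05, and 1 passed the narrower adjustment without old library 2. Cdkn1c, an inhibitor of the cell cycle, had 9.71 ± 1.95 TPM in middle-aged and 24.61 ± 1.35 TPM in old libraries, and the transcription factor Tcf4 157.13 ± 18.31 and 241.17 ± 68.53 TPM.

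Macrophage and myeloid markers, genes of the phagocytes that CD47 restrains, were lower in old than in middle-aged libraries. Of 14 genes 11 were lower (median -1.56, adjusted p = 0.046; adjusted p = 0.47 with an estimated correlation), lost without young library 1 (0.0534), 2 (0.0631), middle-aged library 1 (median 0.00, 0.263), old library 2 (0.0855) or 3 (0.079). It was also lost with a pseudocount of 0.1 (0.0833), a mean of at least 5 TPM (0.38) and a replicate block (0.0654), in a range of 0.0422 to 0.47. By limma 0 passed over all genes and 0 adjusted over the list alone, with 1 at unadjusted p under 0.05, and 2 without either middle-aged library. The lysozyme gene Lyz2 had 68.45 ± 14.43 TPM in middle-aged and 30.86 ± 24.08 TPM in old libraries. The integrin gene Itgam, overlapped by a gene model, was listed at 6.55 and 7.02 TPM against 0.84, 0 and 0.80 TPM, and the MHC class II gene H2-Aa at 36.57 and 13.03 TPM against 0, 9.31 and 11.99 TPM. In this comparison, and so beside the respiratory and quiescence genes too, lymphocyte markers had a median of -1.38 (adjusted p = 0.25), tenocyte markers -0.48 (0.794), endothelial markers -0.40 (0.986) and Schwann cell markers 1.38.

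Single cells of 1 young and 1 old mouse show how transcripts spread over cells, without a test between the ages, since each is 1 animal. Young wells mostly held a cell with many genes: 54 of 64 wells (84.4%, 95% interval 73.1 to 92.2) had at least 1000 genes at 1 TPM or more. In the old mouse 7 of 31 wells did (22.6%, 9.59 to 41.1), and 21 of 31 wells were under 200 genes, against 7 of 64. The median was 1854 genes in young and 64 in old wells, and 1934 and 1820 among wells with at least 1000 genes. Comparisons over all wells therefore mostly carry this difference, and values are given for the 54 and 7 fuller wells as well.

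**Figure D3:**
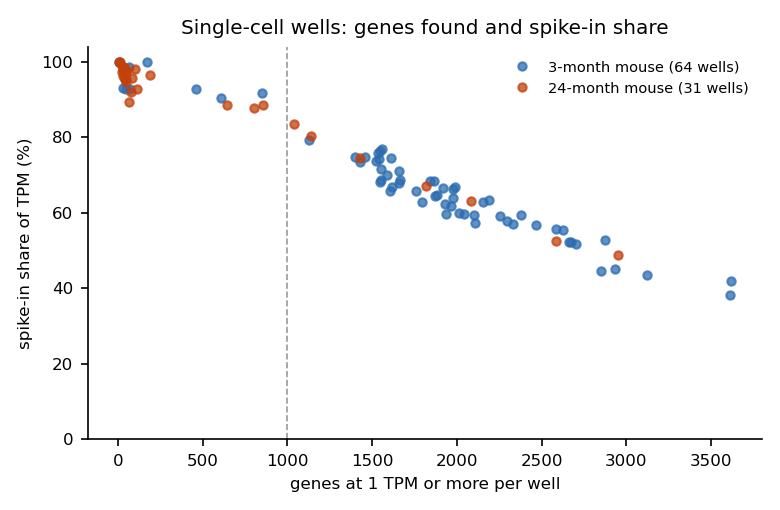
Genes at 1 TPM or more against the spike-in share of TPM in each well of the young and the old mouse; the dashed line marks 1000 genes.

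Cd47 was found in 28 of 64 young wells (43.8%, 31.4 to 56.7) and 3 of 31 old wells (9.7%, 2.0 to 25.8). Its mean log2(TPM + 1) differed by -1.5 over all wells (old minus young), and by -0.47 among fuller wells. In those it was found in 28 of 54 (51.9%, 37.8 to 65.7) and 3 of 7 (42.9%, 9.9 to 81.6). With 1 mouse per age these shares do not say whether ages differ. Because limma called 0 bulk genes for old against young (1325 at unadjusted p under 0.05), there were no bulk calls to follow in the wells. Pax7 was found in 38 of 54 young (70.4%, 56.4 to 82.0) and 5 of 7 old fuller wells (71.4%, 29 to 96.3), and Myf5 in 50 of 54 (92.6%) and 7 of 7 (100%). Cd34 was found in 39 of 54 (72.2%, 58.4 to 83.5) and 2 of 7 (28.6%, 3.7 to 71.0), Cdkn1a in 31 of 54 (57.4%, 43.2 to 70.8) and 1 of 7 (14.3%, 0.4 to 57.9), and Calcr in 24 of 54 (44.4%) and 2 of 7 (28.6%). Myod1 was found in 16 of 54 (29.6%) and 2 of 7, Ptger4 in 6 of 54 (11.1%) and 2 of 7, Thbs1 in 2 of 54 (3.7%) and 0 of 7, which allows a share of up to 42.9%. Mki67 was found in 2 of 54 and 0 of 7, and Sirpa in 0 of 54, which allows up to 5.6%, and 1 of 7. Myog, Cdkn2a and Hpgd were found in 0 of 54 and 0 of 7. Of genes chosen after the bulk values were seen, Osmr was found in 29 of 54 (53.7%) and 2 of 7 wells, B2m in 46 of 54 (85.2%) and 5 of 7 (71.4%), Pmp22 in 29 of 54 and 4 of 7, and Kcna1 and Mbp in 0 of 54 and 0 of 7.

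The genes with the largest differences over all wells are abundant in most cells, and so low in wells with few genes. Of 1627 genes that met the rule, 1627 were lower in the old mouse, from Eef1a1, a translation elongation factor (-6.65), the ubiquitin gene Ubb (-6.51), the syndecan Sdc4 (-6.45), Gpx3, a secreted peroxidase (-6.25), and the actin gene Actb (-6.17) to Mycbp2 (-0.30), a ubiquitin ligase. Among fuller wells 2802 genes met it, 1444 higher and 1358 lower in the old mouse. The most strongly higher were Immt, which shapes mitochondrial cristae (3.4), the splicing factor Snw1 (3.31), the polymerase subunit Pold4 (3.13), the repressor Myef2 (3.00) and the checkpoint protein Topbp1 (2.99). The most strongly lower were the splicing factor Srsf11 (-3.86), Sertad1, a cyclin-dependent kinase cofactor (-3.76), Serping1 (-3.45), Atf3 (-3.37) and the phosphatase Ptp4a1 (-3.18). Of 26 lists over all wells, 2 lay outside the range of 95% of random lists, quiescence and Notch targets (median -0.945, percentile 97.98) and mitochondrially encoded genes (-1.277, percentile 100). Both medians are negative, against a median of -0.97 over 3852 genes. Some of 26 lists fall outside such a range by chance. The genes of a random list were drawn singly, so the range ignores members that move together. Quiescence and Notch targets lay within the range as log2 of the mean (percentile 92.83), with a pseudocount of 10 (96.48), in a shared range of genes (96.06) and without spike-ins (87.52). Mitochondrially encoded genes turned to a median of 0.363 without spike-ins (10 higher, 4 lower), and among fuller wells had 0.094 (percentile 82.97). Among fuller wells, where the median of all genes was -0.26, immediate early genes (-1.278, percentile 0.03, 25 of 25 lower) and heat shock genes (-1.08, percentile 2.18, 16 of 16 lower) lay outside it. Without spike-ins these were at percentiles 0.14 and 3.12, and over all wells at 43.9 and 67.63, or at 4.38 and 0 as log2 of the mean (16 of 16 heat shock genes lower).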

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

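All tests of the wells in this part were chosen after the result was seen, and the splits of the libraries were planned. Spike-in RNA, which the comparisons do not use, was found in 3 bulk libraries: 47.24 TPM in middle-aged library 1, 15.27 TPM in old library 1 and 13.16 TPM in old library 3. The other 5 bulk libraries list 0 TPM for it. In the wells, spike-ins took a median of 95.55% of TPM in the old mouse and 66.56% in the young mouse.

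The pattern in the wells is that 21 of 31 wells of the old mouse held fewer than 200 genes. Of these, 1 (4.8%) had Actb at 1 TPM or more, as did 2 of 7 such wells of the young mouse. Since the wells were picked for few genes, this does not tell wells without a captured or amplified cell from poor amplification or low RNA content. A lower RNA content of the old mouse's cells in general cannot be told apart either, since 9.68% of its wells (3 of 31) held 200 to 1000 genes and the animal is 1. Nor can a difference between the 12 sets of the N7 index, since 0 of them hold wells of both ages: 8 hold young wells and 4 old ones. In old sets 9, 10, 11 and 12, wells with at least 1000 genes numbered 4 of 8, 0 of 8, 2 of 8 and 1 of 7. Young sets had 6 to 8 of 8. The old sets thus differed among themselves, with few wells in each. Every set of the N5 index holds both ages, and in each a smaller share of old wells had at least 1000 genes. The shares were closest in set 1 (2 of 3 old, 7 of 8 young) and furthest apart in set 5 (0 of 4, 8 of 8). Because the N5 sets hold the 2 ages in nearly the same proportion, position along that index alone could hardly give the difference. That follows from the layout, and the counts above add no evidence to it. The age of the mouse stays open, untested, and values over all wells carry whichever of these applies.

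For old against young libraries, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 genes with limma, and the highest other split 1. With a real count of 0 every split gives as many, so the count of called genes decides nothing. At unadjusted p under 0.05 the real split had 1325 genes and the others 667 to 1015. Those others mix ages within a group, which widens their spread. For gene lists, the real split called 13 and the highest other 7, so 1 of the 10 splits, the real one, gave as many.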

How the results depend on the processing

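The values rest on 2 or 3 libraries per age without known depth, with many genes listed at 0 in part of them, and on 1 mouse per age for wells. For old against young, 0 genes passed in limma under every one of 22 alternatives (1325 at unadjusted p under 0.05 as reported), and Cd47 stayed higher, by 0.74 to 0.79 log2 units and by 0.65 to 0.90 without 1 library. Over named genes, 2074 of 2113 values kept their direction and side of the threshold, 14 became weaker, 15 stronger and 10 reversed. Of the 98 named results, only 1 was past the threshold as reported, Mapkapk3 for middle-aged against young. That call stayed in 7 of 21 alternatives, and its losses are the 14 weaker values. For the other results, keeping the side of the threshold means only that they stayed uncalled. Of 418 values for the lists past the threshold, 293 stayed, 125 became weaker and 0 reversed in the direction of the test. A median changed sign in 1 of them: quiescence and Notch targets for old against middle-aged had -0.07 without middle-aged library 2 (0.32 as reported). The estimated correlation weakened 25 of 25 and fry 15 of 25. Without 1 library 144 of 200 stayed. Except where fewer genes or samples entered, the cause was not tested. The filters at a mean of 20 TPM and on values above 0 in all 8 libraries, and the rescaling without spike-ins, were chosen after seeing the data.

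Genes past the threshold for middle-aged against young (1 as reported) were 7 with a pseudocount of 0.1 (2 higher, 5 lower), 0 with 5, 0 without a filter, 2 with a mean of at least 5 TPM, 5 after quantile normalization, 0 after median-ratio scaling, 0 without mitochondrial and ribosomal protein genes and 0 with only the 2 groups. They were 12 without a trend of the variance, 8 with a robust fit and 0 with library weights. For old against middle-aged (0 as reported) they were 6 with a pseudocount of 0.1, 1 after quantile normalization and 1 with a robust fit. Leaving out 1 library gave 0 to 859 and 0 to 792. Without middle-aged library 1 there were 600 and 580 genes, and 859 and 792 without middle-aged library 2. Of these, 567, 538, 821 and 749 had an age group listed at 0 throughout. In those fits the lone middle-aged library is assumed to vary like the other groups.

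A block for the replicate number, which does not pair libraries, gave 0 genes for middle-aged against young, and 13, 6 and 3 lists for old against young, middle-aged against young and old against middle-aged (13, 7 and 5 as reported). With it, stem cell identity at middle age had an adjusted p of 0.0828 (range over its alternatives 0.00866 to 0.643).

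Lists past the threshold for old against young were 0 with an estimated correlation, 8 with a mean of at least 20 TPM, 7 with values above 0 in all 8 libraries, and 8 to 14 without 1 library. For middle-aged against young they were 0 with an estimated correlation, 3 by fry, 3 with values above 0 in all 8 libraries and 0 to 8 without 1 library. For old against middle-aged they were 3 with a pseudocount of 0.1, 3 with a mean of at least 5 TPM, 3 with a mean of at least 20 TPM, 0 with an estimated correlation, 0 by fry and 0 to 6 without 1 library. The filter at a mean of 20 TPM left 28 lists to test and that on values above 0 left 32, of 36, so tenocyte markers had no value under either. Lists gained for old against middle-aged were prostaglandin E2 genes (lower, 0.015 with a mean of at least 5 TPM), ribosomal protein genes (lower, 0.00334 with a mean of at least 20 TPM), and autophagy genes without mitochondrial and ribosomal protein genes (0.045), in ranges of 0.015 to 0.808, 0.00334 to 0.989 and 0.045 to 0.821.

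Directions that reversed did so without 1 library. For old against young these were Cd34 (-0.58 to 0.06), Myod1 (-0.90 to 0.21), Sirpa (-0.47 to 0.60) and Myog (-1.02 to 1.5). Cd47 for middle-aged against young had -0.19 to 0.01, and for old against middle-aged Cdkn1a had -1.10 to 1.58 and Pax7 -0.10 to 0.75.

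In the wells, Cd47 (-1.5, old minus young, as reported) differed by -2.97 as log2 of the mean, -0.66 with a pseudocount of 10, -0.47 in wells with at least 1000 genes, -1.36 in wells of a shared range of genes, -2.0 without spike-ins and -0.72 with both. Its share of young wells was 43.8% as reported, 26.6% at 10 TPM or more and 51.6% above 0 TPM. Lists outside the random range (2 as reported) were 1 with a pseudocount of 10, 1 in the shared range and 1 without mitochondrial and ribosomal protein genes.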

Other observations

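The tests chosen after the result was seen are those of correlated residuals, of Schwann cell genes in the wells and of dissociation, and the test of Cd47 against 5 libraries; that of scaling was planned. Some genes had their highest or lowest values at middle age. Of 4393 genes with a mean of at least 20 TPM, both middle-aged libraries were the highest 2 of 8 for 225 (5.12%) and the lowest 2 for 175 (3.98%), where chance gives 3.57%. Trib1, a pseudokinase that directs protein degradation, chosen after its values were seen, had 43.31 ± 3.08 TPM in young, 307.64 ± 57.01 TPM in middle-aged and 106.78 ± 18.98 TPM in old libraries. Its adjusted p for middle-aged against young was 0.0893, with a range of 0.00197 to 0.292 over the alternatives. Cd47 in the 3 old libraries lay above the other 5 libraries. A permutation test of that order, run after it was seen, gives the smallest exact p that 56 splits allow, 0.018, and adds nothing to it. Of the sex-linked genes, Xist was found at 397.02 to 1289.21 TPM in the 8 libraries, and Kdm5d, Uty, Ddx3y and Eif2s3y were listed at 0 in all of them.

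Schwann cell genes were higher in the old bulk libraries, by a median of 2.55 log2 units. Scaling of the libraries as the whole cause is argued against: under the 3 other scalings the lowest median was 2.5 and the highest 2.8. Cells of another type in the samples are a candidate explanation that stays unsettled. The members moved together between libraries of an age (median correlation of residuals 0.65, percentile 100 of 1000 matched lists, whose median was 0.05). Genes under shared control within the stem cells would move together too. The random lists were matched on expression alone, so the correlation does not tell these apart. The abundant Pmp22 and Mbp reached 5013.11 and 288.21 TPM in old library 2, the labels state no sort gate that would remove glia, and 0 of the 11 members belong to another list, though 4 were found in at least 1 of the fuller young wells. Expression spread over most old muscle stem cells cannot be told apart: the 7 fuller old wells gave 4 detections of 77 possible, all of Pmp22, against a median of 29 for matched lists (percentile 0), but come from 1 mouse, and the age of the mice stays open, untested.

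JAK-STAT and interleukin 6 genes were higher in old bulk libraries by a median of 0.70 log2 units. A stronger response to dissociation in the old libraries cannot be told apart from age. The 6 abundant immediate early genes (Dusp1, Egr1, Fos, Fosb, Jun and Zfp36) had a median difference of 0.09 (spread 0.12), below 0.35, the level set for that explanation after values were seen. The 28 immediate early genes together had a median of 0.32 and passed the threshold, and the labels give no dissociation time, which keeps it open. Among fuller wells, the immediate early genes went the other way and were lower in the old mouse. With 1 mouse per age, the wells cannot decide this for the bulk libraries. RNA from other cell types stays open too, as Schwann cell, tenocyte and fibroblast markers were higher in the same libraries (medians 2.55, 1.47 and 0.91).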
